A study of Drosophila melanogaster with 2 samples.

How the data were processed

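ChIP-seq libraries were made from whole Drosophila melanogaster embryos (0 to 24 h, both sexes) of a line carrying Lbe fused to GFP, with an antibody against GFP; chromatin was sonicated and fragments of 200 to 800 bp were kept, per the labels. There is 1 group with 2 biological replicates, each with its own embryo sample, numbered as the labels give them. A control is named for the calling, per the labels; the control was not analysed here.

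The authors deposited region lists in narrowPeak format, in dm3 and in dm6, with up to 30000 regions each: peak and background regions called on each replicate, the same for both replicates pooled, and peaks past the IDR threshold made from both replicate lists and the pooled list. The aligner, the peak caller and their versions are not given in the sources used here. Each region has the signal that the authors' peak caller gave it against the control, on a scale not stated, so signals were used only to rank and describe regions within a list. Each region also has a q-value as −log10, as deposited; all 4782 IDR peaks of dm6 carry the same, highest −log10 q-value, so it was not used for ranking. The summit is the deposited offset from the start of the region. The files hold no read counts, so depth is unknown and intervals on shares cover only the counting of regions.

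The main analysis used dm6. Positions were compared with the Ensembl release 115 annotation BDGP6.54 and the release 6 genome sequence; all dm6 regions on 2L, 2R, 3L, 3R, 4, X and the mitochondrial genome ended within the reference lengths. The dm3 lists were used for counts and overlaps alone, with no conversion of positions. Analyses of location, genes and words used the 4753 IDR peaks on the 6 nuclear chromosome arms. This restriction was made after the data were examined, since 29 peaks were mitochondrial.

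Replicates were compared with the 4782 strongest regions of each list, as many as there are IDR peaks, counting a summit as shared within 200 bp. Random expectation came from 100 placements. Promoter and category shares were compared with 1000 random placements of the summits on the same chromosomes outside gaps, with two-sided permutation tests. The categories were, in order, promoter (within 500 bp of a TSS of a protein-coding or non-coding RNA gene), 5′ UTR, 3′ UTR, coding exon, intron, other exon and intergenic. Densities per Mb have exact Poisson intervals, and shares have 95% Wilson intervals; for a count of 0, the text gives 3 counts over the total, which lies below the Wilson limit drawn in the figure.

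The 14 gene lists were tested with two-sided Fisher's exact tests over 13945 protein-coding genes, with a window of 1000 bp around any TSS. From the FGF, EGF and Notch list 1 gene, Dl, was not found in the annotation under the symbol written. It was left out of that list. The 10 words were tested on either strand within 100 bp of the summit, against the lower-coordinate window centred 600 bp away, by exact McNemar tests; printed flank shares are means of both sides. Benjamini-Hochberg adjustment ran over the lists and over the words, with a threshold of 0.05. The difference of median signal was tested with 100000 permutations. Peaks and genes are treated as independent in these tests, and p-values do not measure spread between embryos.

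The tests, gene lists and words were fixed before the data were examined, as was the rule for named items. It names the 20 IDR peaks with the highest signal, each IDR peak within 10000 bp of lbe or lbl, up to 4 genes per list with the highest signal and, for lists past the threshold, up to 4 without a peak, and the 5 most raised 6-letter words among those at 5% or more of summits. Because 19 of the first 20 peaks were mitochondrial, the 20 strongest on the chromosome arms were named in their place.

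Alternatives were other TSS windows, other overlap rules, the stronger 2376 peaks, each replicate's list alone, protein-coding TSSs alone, gene bodies with length-matched random lists, the nearest TSS, narrower word windows, the other flank, and peaks inside or outside promoters. Added after the data were seen were the weakest pooled regions as comparison, genes with any pooled region as background, nearest-TSS lists matched on territory, category shares per replicate and in the stronger peaks, chromosome densities per replicate, mitochondrial peaks included, words of the same letters, and further gene families.

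The tests were tested on simulated data. With 49.9% of 4753 summits put at promoters, the promoter test recovered 49.9%, and it called 1 of 20 random sets. Of 200 simulated lists of 20 genes with 60% occupancy, among 13945 genes, the list test called 176. It called 4 of 200 lists drawn at random, with a background occupancy of 24.6%. Planted and random lists were adjusted together in equal numbers, which makes recovery easier than where few lists are raised. For lists of long genes where occupancy followed length alone, the length-matched test called 5 of 200 and the unmatched test 111. These calls used p under 0.05 without adjustment. A word put at 5% of 4753 random summits was called in 20 of 20 runs, with 3 calls among 180 tests of other words. Random positions lack the A and T excess of the real summits (62.9% against 56.8% in flanks). The rate of calls among other words thus does not cover calls that come from base composition.

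Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.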

Results

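Ladybird early (Lbe) is a homeodomain transcription factor of the Drosophila NK homeobox cluster, known for its part in specifying muscle and heart cells. Its binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole embryos aged 0 to 24 h, of both sexes. The embryos came from a transgenic line in which GFP is fused to the C-terminus of Lbe, and the precipitation used an antibody against GFP. The series holds 1 group of 2 biological replicates. There was no second condition, so the comparisons are between the replicates, and between the peaks and the rest of the genome. The files list regions and not reads, so the read depth of each library is unknown. All positions are in dm6, and the signal of a region is the value the authors' peak caller gave it, on a scale the sources used here do not state.

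The authors' list of peaks past the irreproducible discovery rate (IDR) threshold held 4782 peaks, and 4781 of them were among the 4782 strongest regions of the pooled list. Of these, 4753 lay on the chromosome arms 2L, 2R, 3L, 3R, 4 and X, and 29 lay on the mitochondrial genome. The median peak was 410 bp wide. Signals ran from 98.7 to 1790.2 on the chromosome arms, with a median of 147 over the whole list. The mitochondrial genome took 19 of the 20 highest signals, so the 20 strongest peaks on the chromosome arms, a set chosen after the values were seen, are described here.

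Of those 20 peaks, 14 had their summit in a promoter, 4 in an intron, 1 in another exon and 1 between genes. The strongest lay in an intron of CG11050 (2L, 6612342 to 6612922, signal 1790.2), and the next at the promoter of CG14100 (3L, 19590439 to 19590820, signal 1632). A peak of signal 1467 (2L, 480923 to 481295) lay in an intron of ush, which encodes a cofactor of GATA factors, 1362 bp from the nearest transcription start site (TSS), that of cbt. Promoter peaks followed at CG18549 (signal 1429), lncRNA:CR31044 (1395), PNPase, a mitochondrial RNA-processing enzyme (1378), and Ugalt, a UDP-galactose transporter (1298). The intron peak of CG32772 had a signal of 1228.

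The small heat shock gene Hsp27 (3L, 9383719 to 9384097) had a promoter peak of signal 1208, and CenG1A one of 1207. The promoters of CG9147 (1193), CG1888 (1168), the glycolytic gene Gapdh2 (1100.3), the chromatin protein gene Chro (1086), lncRNA:CR44619 (1082), the Polycomb group gene ph-p (1071) and CG11309 (1029.5 signal) were also in this set. The remaining peaks lay in an exon of lncRNA:CR46035 inside osa (signal 1142), 3796 bp from CG31668 between genes (1121), and in an intron of Lk6, a kinase gene (1076). Each of the 20 peaks matched a region among the 55 strongest of both replicate lists.

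The replicates were compared by the rank of their regions, since each was called on its own. Of the 4782 strongest regions of replicate 1, 59.2% (95% Wilson interval 57.8 to 60.6) had a summit within 200 bp of a summit among the 4782 strongest of replicate 2. In the other direction the share was 61.0% (59.6 to 62.4). Summits placed at random on the same chromosomes met a share of 1.41% on average and at most 1.85% over 100 placements. Of the 4753 IDR peaks on the chromosome arms, 2709 were among the 4782 strongest regions of both replicates, 1175 of replicate 1 alone, 701 of replicate 2 alone and 168 of neither. Ranks could lie far apart, as for the peak at ptc (rank 29387 in replicate 1 and 1079 in replicate 2). Among the 1188 strongest of these peaks, 96.5% were in the top set of both replicates, against 9.92% of the 1189 weakest. The groups were cut by the pooled signal, which is made from both replicates, so part of this contrast is built in. Across the peaks matched in both lists, which are not independent replicates, Spearman's rho of the signals was 0.40. It was -0.704 in the weakest group and 0.490 in the strongest. The cut by pooled signal bears on these values too. Peaks of similar pooled signal that are higher in 1 replicate tend to be lower in the other. The value of -0.704 therefore does not show that the replicates rank weak peaks in opposite order. Intervals here cover counting error only.

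The replicates' strongest regions differed in base composition. Within 100 bp of the summit, A and T made up 64.5% of bases in replicate 1 (SD 6.22 across 4753 regions) and 59.5% in replicate 2 (SD 8.30 across 4750 regions). Windows 600 bp away held 56.5% and 57.6%. The word TAATTA lay at 17.7% of replicate 1 summits and 11.7% of replicate 2 summits, and GAGAGA at 11.3% and 20.5% (Fisher's exact test with Benjamini-Hochberg adjustment over 10 words, adjusted exact p = 4.37e-16 and 4.11e-34). These p-values treat regions as independent and compare 2 libraries. The test was unpaired, although 59.2% of the replicate 1 summits had a replicate 2 summit within 200 bp.

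Most Lbe-GFP peaks on the chromosome arms lay at promoters. Of 4753 summits, 2627 were within 500 bp of a TSS, a share of 55.3% (53.9 to 56.7). Random placements on the same chromosomes gave 13.2% (11.5 to 14.8 over 1000 placements), so promoters held 4.19 times the expected share (two-sided permutation test, p = 0.002, the smallest that 1000 placements allow). The weakest 10000 regions of the pooled list, a comparison added after the data were seen, had 18.4% of their summits at promoters. The promoter share was 55.5% in the strongest regions of replicate 1 and 54.3% in those of replicate 2.

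Coding exons held almost no peaks. They took 4 of 4753 summits, or 0.0842% (0.0327 to 0.216), against 13.1% of random positions. Summits were also below the random share in introns (30.8% against 39.5%), between genes (11.3% against 27.6%) and in 3′ UTRs (1.05% against 5.04%), each with an adjusted permutation p of 0.0028. Summits in 5′ UTRs (0.905% against 0.774%, adjusted p = 0.34) and in other exons (0.589% against 0.767%, adjusted p = 0.196) did not pass this permutation test. In the weakest pooled regions coding exons held 3.02% of summits.

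**Figure D1:**
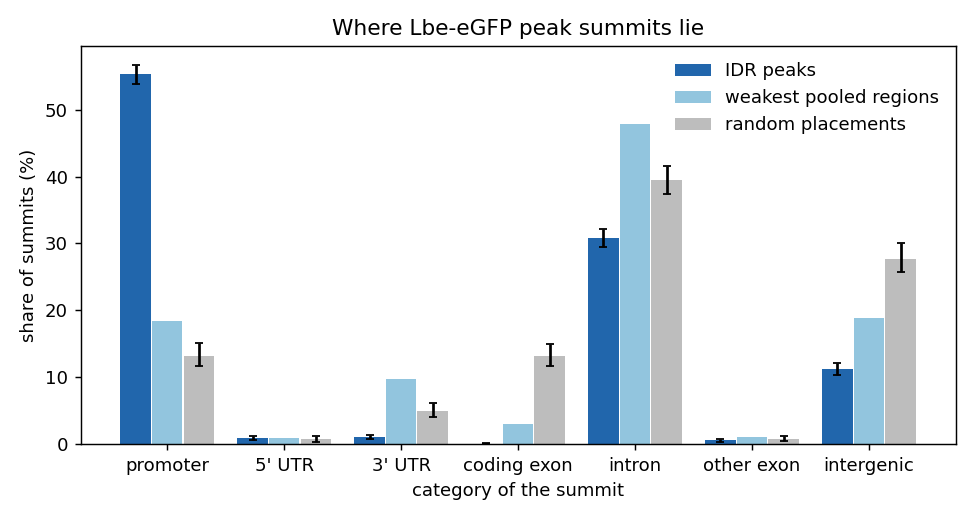
Share of summits (%) in each category for the 4753 IDR peaks (error bars, 95% Wilson interval), the weakest pooled regions (no error bars) and random placements (bars, mean; error bars, lowest and highest of 1000). Promoters held 55.3% of IDR summits against 13.2% of random positions, and coding exons 0.0842% against 13.1%.

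The large arms carried similar densities of IDR peaks, at 37.7 per Mb on 2L, 35.7 on 2R, 37.1 on 3L and 35.4 on 3R. The X chromosome had 32.7 per Mb (95% exact Poisson interval 30.4 to 35.1). Chromosome 4, a small and largely heterochromatic chromosome, had 21 peaks, or 15.8 per Mb (9.77 to 24.1). None of the lists held a region on the Y chromosome, including the lists with background regions, so no density is given for it. In the full replicate lists chromosome 4 held 600 regions in replicate 1 and 91 in replicate 2, against 27 and 14 among the 4782 strongest.

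Signal differed little between promoter peaks and the rest. The median was 148 at promoters and 144 elsewhere, a difference of 4.07 (permutation test across peaks, p = 0.0325, which treats peaks as independent). This call was lost with a TSS window of 200 bp (difference 0.442, permutation p = 0.812) and with the matched signals of replicate 1 alone (2.48, p = 0.0678), and the sign turned with those of replicate 2 alone (-0.157, p = 0.873). It does not hold up against the spread between replicates.

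Gene lists fixed in advance were compared by whether a gene had an IDR summit within 1000 bp of a TSS. Ribosomal protein genes stood out: 57 of 78 (73.1%) had such a peak, against 24.2% of the other protein-coding genes (Fisher's exact test, adjusted p = 2.45e-18 over 14 lists). The strongest were at RpL32 (3R, 30046114 to 30046499, signal 439), RpS19b (350.02), RpL24 (345) and RpL19 (343). The RpS19b summit (3R, 23934423) fell in the intron category and outside the gene itself (23932729 to 23933530). Its assignment rests on the 1000 bp window. RpL10, RpL15, RpL21 and RpL22 had none. Odorant and gustatory receptor genes, which serve the adult and larval senses, were the opposite: 0 of 119 had a peak, which allows up to 2.52% at 3 counts (adjusted exact p = 2.74e-14). Gr10a, Gr10b, Gr21a and Gr22a are examples. Both calls held with each replicate's list alone, where 2 of these receptor genes had a peak in replicate 1 and 1 in replicate 2.

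With this window, none of the preset lists of muscle, heart and signalling genes passed the test against other genes. Of 22 muscle identity factors, 4 (18.2%) had a summit within 1000 bp of a TSS, at Poxm (signal 235), sd (225), org-1 (161) and lbl (133). Of 18 mesoderm and heart factors, 3 (16.7%) did, at the heart gene tin (491) and the GATA factor genes srp (115.4) and pnr (104). Of 18 genes of myoblast fusion and adhesion, 5 (27.8%) did, among them Msp300 (348), the integrin gene mys (135), mbc (122) and WASp (120.3). The contractile apparatus had peaks at 2 of 20 genes (10%), Zasp52 (206) and Tm1 (153). Adjusted p-values from Fisher's exact test were 0.844, 0.844, 0.844 and 0.559. When summits in the gene body or up to 2000 bp upstream were counted, against random lists matched on gene length, the contractile apparatus passed as lower (10% against 38.7%, adjusted permutation p = 0.0476).

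The signalling and patterning lists did not pass with this window either. The FGF, EGF and Notch list had 8 of 21 genes with a summit within 1000 bp of a TSS (38.1%, adjusted exact p = 0.559), led by the EGF ligand gene spi (377), pnt (199), E(spl)m7-HLH (195) and aos (170.4). The segment polarity and Wnt list had 5 of 20 (25%, adjusted exact p = 1), led by nkd (207), fz3 (178), ptc (119) and fz2 (112). Of 12 Hox genes and cofactors, 2 had a peak (16.7%, adjusted exact p = 0.844), cad (107) and hth (102).

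Nor did lists of other tissues. Peaks lay within 1000 bp of a TSS at 3 of 22 neural factors (13.6%, adjusted exact p = 0.754), elav (480.0), grh (167) and nub (107), and at 2 of 12 genes each of epidermis and cuticle, shn (630) and Cad99C (112), and of gut and fat body, fkh (311) and srp (16.7% and adjusted exact p = 0.844 for each). None of 16 chorion and yolk protein genes had a peak, which allows up to 18.8% at 3 counts (adjusted exact p = 0.0821).

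In the strongest regions of replicate 2 alone, 10 of 18 fusion and adhesion genes (55.6%, adjusted exact p = 0.0101) and 10 of 21 signalling genes (47.6%, adjusted exact p = 0.0491, Fisher's exact test) passed; in replicate 1 alone these were 27.8% and 42.9%. Measured against the IDR peaks, the shares of some other lists moved by over 1.5 times with a single replicate. Mesoderm and heart factors were at 5.56% in replicate 1 and 22.2% in replicate 2, and the NK cluster at 16.7% and 50%. Segment polarity and Wnt was at 20% and 40%, and Hox genes at 8.33% and 16.7%. Neural factors were at 9.09% and 22.7%, and gut and fat body at 8.33% and 25%. Muscle identity factors moved less, from 18.2% to 13.6% in replicate 1 and 22.7% in replicate 2. When peaks went to the gene with the nearest TSS instead, the mesoderm and heart list rose from 16.7% to 55.6%, the segment polarity and Wnt list from 25% to 60%, and the FGF, EGF and Notch list from 38.1% to 52.4%, each against 21.8% of other genes (adjusted exact p = 0.00587, 0.00116 and 0.00587). Against random lists matched on the territory nearest to each gene, a test added after the data were seen, these lists did not pass (adjusted permutation p = 0.12, 0.0803 and 0.12).

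**Figure D2:**
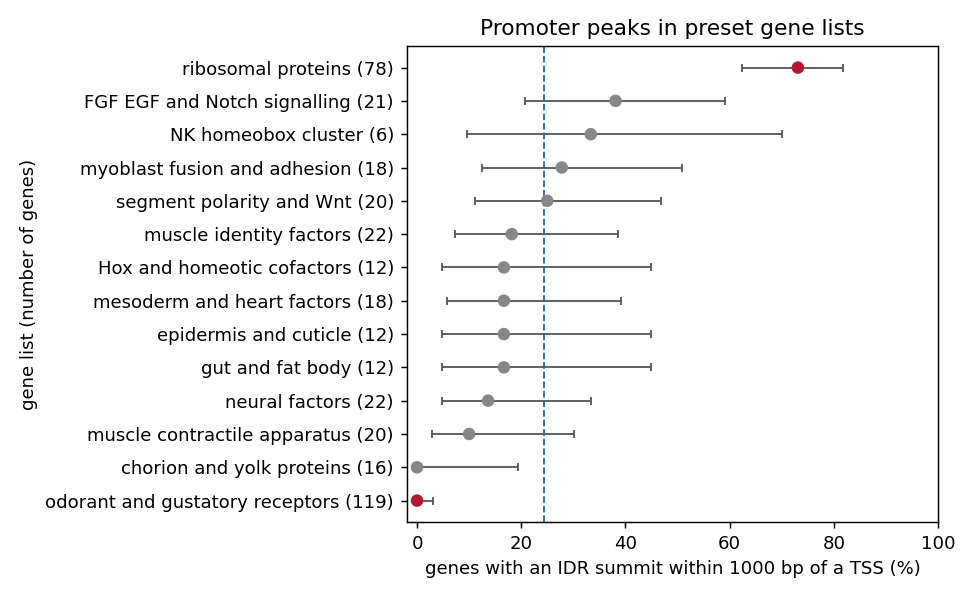
Percent of genes with an IDR summit within 1000 bp of a TSS in 14 preset lists, with the number of genes in parentheses; lines are 95% Wilson intervals, red points have an adjusted p under 0.05, and the dashed line is the share of other protein-coding genes (24.4%). Ribosomal protein genes lie at 73.1% and odorant and gustatory receptor genes at 0.

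The tagged gene's own neighbourhood had 3 IDR peaks of moderate rank. Within 10000 bp of lbe and its neighbour lbl, peaks lay in an intron of lbl (3R, 21419872 to 21420281, signal 125, rank 3231), at the lbl promoter (21434201 to 21434610, signal 133, rank 2886) and between genes 5824 bp from the lbe TSS (21452156 to 21452565, signal 135, rank 2813). The gene body of lbe and the 2000 bp to either side held 0 regions of the dm6 lists. The tag came with a transgene, so this locus can carry extra copies. Their effect on the regions called was not measured, so the 0 does not show that Lbe leaves its own gene unbound. The strongest region of the locus ranked 1809 in replicate 1 and 1201 in replicate 2, and these were different regions.

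Elsewhere in the NK homeobox cluster, tin had the strongest peak, at its promoter (21378603 to 21378897, signal 491, rank 167). Intergenic peaks flanked C15 at 21493502 to 21493911 (signal 248, rank 810) and 21520246 to 21520469 (signal 289, rank 579). The first had no matching region in the replicate 2 list, and the second lay 549 bp from the TSS of sp3. Peaks within 1000 bp of a TSS were present at 2 of the 6 cluster genes (33.3% against 24.4%, Fisher's exact test, adjusted p = 0.844).

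**Figure D3:**
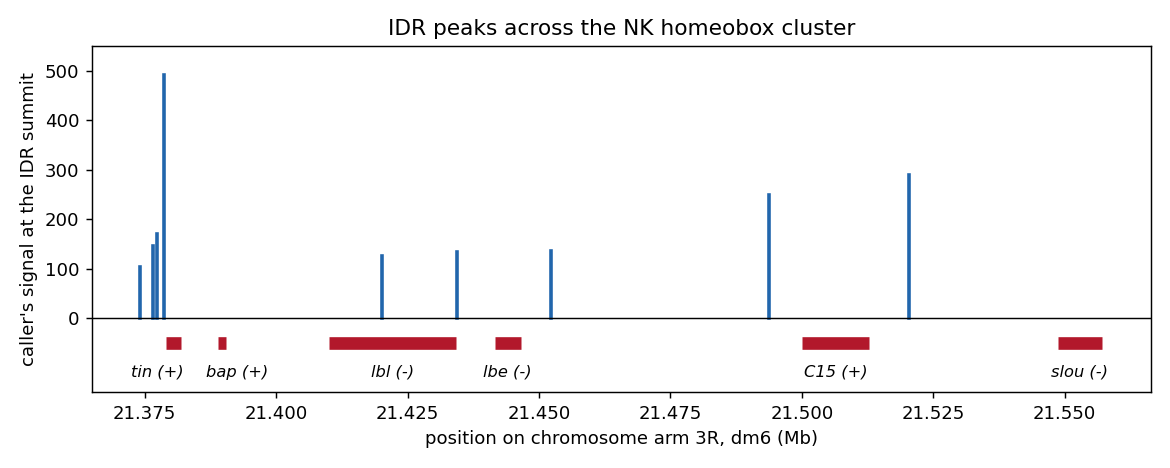
IDR peaks (blue lines, height is the caller's signal at the summit) and the 6 NK cluster genes (red bars, with strand) on arm 3R in dm6. The promoter peak of tin reaches 491, and no IDR peak was called on lbe itself, a locus that can carry extra copies from the transgene.

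Peak sequences were searched for 10 words fixed in advance, within 100 bp of the summit against windows 600 bp away. The DRE word TATCGATA, bound by the promoter factor Dref, was the most raised, at 5.05% of 4753 summits against 0.6% of flanks (8.42-fold, exact McNemar test, adjusted p = 5.94e-45). Motif 1, GGTCACAC, another core promoter element, followed at 2.76% against 0.621% (4.44-fold, adjusted exact p = 7.66e-18). The GAGA word GAGAGA lay at 15% of summits against 8.98% of flanks (1.67-fold, adjusted exact p = 2.44e-16). The GATA word AGATAA was 1.13-fold higher (adjusted exact p = 0.00898) and the Zelda word CAGGTA 0.833-fold (adjusted exact p = 0.0398), but both calls were lost against the flank on the other side. The words TCAAGTG, CAGCTG and CACACA did not pass in the full set, at 1.08-fold, 1.09-fold and 0.931-fold. CAGCTG did pass at promoter peaks (1.28-fold, adjusted exact p = 0.00313) and in the strongest regions of replicate 2 (1.21-fold, adjusted exact p = 0.00025). CACACA passed in opposite directions in the replicates, at 0.839-fold in replicate 1 and 1.24-fold in replicate 2 (adjusted exact p = 0.00246 and 2.62e-08), and as lower within 50 bp of the summit (0.825-fold, adjusted exact p = 0.0229).

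The homeodomain core TAATTA lay at 15.6% of summits against 11.2% of flanks (1.40-fold, adjusted exact p = 3.72e-10), and the ladybird-type word TAACTA at 11.4% against 8.85% (1.29-fold, adjusted exact p = 2.15e-05). All 14 words made of 3 A and 3 T were more frequent at summits than in flanks, with TAATTA the lowest of them; ATATTA was the highest, at 1.98-fold. Both words were raised in the strongest regions of replicate 1 alone (1.63-fold and 1.47-fold) and not in those of replicate 2 (0.957-fold and 0.998-fold, adjusted exact p = 0.633 for each).

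DRE and Motif 1 lay mostly at promoter peaks. Both are core promoter elements, and promoters without a peak were not compared. The contrast therefore does not set these promoters apart from others. DRE lay at 8.83% of 2627 promoter summits and at 0.376% of 2126 other summits, and Motif 1 at 4.72% and 0.329% (Fisher's exact test, adjusted p = 9.91e-50 and 8.90e-24). The E-box CAGCTG lay at 14.2% and 7.06% (adjusted exact p = 6.76e-15). GAGAGA passed in the other direction, at 13.8% and 16.5% (adjusted exact p = 0.0224), while TAATTA, at 16.1% and 14.96%, did not pass (adjusted exact p = 0.309). Outside promoters GAGAGA alone passed the comparison with the flank. Of all 6-letter words present at 5% or more of summits, the most raised were CGATAG (2.48-fold), TATCGA (2.16-fold), ATCGAT (2.04-fold), ACACTG (2.03-fold) and ATATTA. In the strongest regions of replicate 1 CGATAG also led (2.86-fold). In those of replicate 2 GAGAGA (2.35-fold) and AGAGAG (2.34-fold) led, and CGATAG was at 2.00-fold.

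**Figure D4:**
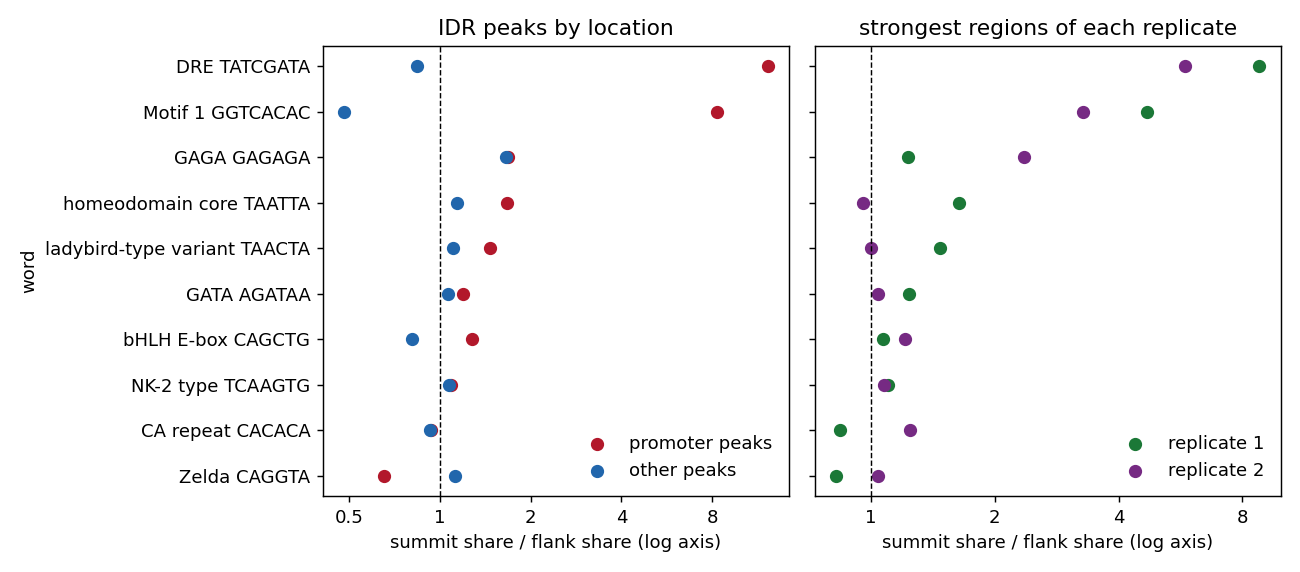
Ratio of the share of summits with a word to the share of flanks (log axis) for 10 words; left, IDR peaks at promoters (red) and elsewhere (blue); right, the strongest regions of replicate 1 (green) and replicate 2 (purple). DRE reaches 12.2-fold at promoters against 0.842-fold elsewhere, and TAATTA is at 1.63-fold in replicate 1 and 0.957-fold in replicate 2.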

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

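The tests of the mitochondrial peaks were chosen after the result was seen. The flag was for signal outside the chromosome arms that the comparisons use: 29 dm6 IDR peaks lay on the mitochondrial genome. Counts above 3 were flagged, a set limit and not a test. Of the 29 peaks, 25 shared the interval from 1 to 15734, with signals up to 14645.7. All 29 peaks together covered 88.7% of the mitochondrial genome. In dm3 the 12 mitochondrial IDR peaks were separate and covered 19.7%, so discrete binding sites stay open; coverage in dm6 was 4.51 times higher for lists from the same replicates, and the authors' mapping and calling for each build may account for part of the pattern. A different content of mitochondrial DNA in ChIP and control libraries stays open too, since regions of single replicate lists covered from 15.4% (replicate 1, dm3) to 88.2% (replicate 2, dm6) and the control was not analysed here.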

How the results depend on the processing

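The calls for 5 genomic categories and the calls for ribosomal protein and receptor genes kept their direction and their side of the threshold under each alternative run, as did the promoter share where it was tested, and the chromosome 4 density stayed within its interval with either replicate left out. With a TSS window of 200 or 1000 bp the promoter share was 42.9% or 65.3%. The comparison of this share with the weakest pooled regions and its value with the mitochondrial peaks (54.9%) had no test. Of the categories not called, 5′ UTRs turned to lower in the stronger peaks (0.673%), and other exons ran from 0.589% to 0.884% with a replicate left out, the higher value above random. Read depth is unknown, so its effect could not be measured; the cause of the changes given here was not tested, except where an alternative's construction sets it.

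By construction, the stronger part of the IDR list held 2391 peaks. The overlap of replicate 1 with replicate 2 was 62.3% when 1 shared bp was enough and 39.0% when summits had to lie within 50 bp. The number of gene lists past the threshold, 2 in the report, was 5 by nearest TSS, where mesoderm and heart factors turned from 16.7% (lower than other genes) to 55.6% (higher), ran from 2 to 4 when a replicate was left out, and was 3 by gene body, where the contractile apparatus passed as lower. Against random lists matched on territory, an alternative added after the data were seen, that 55.6% compared with 30.6% (adjusted permutation p = 0.12). Other lists turned direction without passing in either setting. By gene body, the NK cluster (33.3%) and segment polarity and Wnt (30%) were lower. By nearest TSS, muscle identity (40.9%, also with matched territory), neural (27.3%), Hox (25%) and epidermis (25%) lists were higher. Segment polarity and Wnt was lower with a TSS window of 500 bp (20%), the stronger peaks (10%) and the pooled background (33.3%), and fusion and adhesion was lower with the stronger peaks (5.56%) and that background (29.4%). With a replicate left out, the NK cluster ran from 16.7% to 50%, segment polarity and Wnt from 20% to 40%, muscle identity from 13.6% to 22.7%, neural factors from 9.09% to 22.7% and gut and fat body from 8.33% to 25%, lower than other genes at the low end and higher at the high end; epidermis was at 25% in both, and higher without replicate 1. The best rank in the lbe locus, 2813 in the IDR list, was 1201 without replicate 1 and 1809 without replicate 2.

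The signal difference between promoter and other peaks (4.07) was 0.442 with a window of 200 bp, 2.59 with 1000 bp, and from -0.157 to 2.48 with a replicate left out; none of these passed the threshold. Of the 10 words, 7 passed in the report and 1 outside promoters, where DRE (0.842-fold), Motif 1 (0.483-fold), Zelda (1.12-fold) and CAGCTG (0.806-fold) turned direction. CAGCTG also turned in the stronger peaks (0.984-fold), and TCAAGTG with the window of 50 bp (0.901-fold). With a replicate left out, TAATTA ran from 0.957-fold to 1.63-fold, Zelda from 0.821-fold to 1.04-fold and the CA repeat from 0.839-fold to 1.24-fold, the higher value without replicate 2 for TAATTA and without replicate 1 for the others. Among the results for single words, 47 kept direction and side of the threshold, 10 lost and 4 gained a call, and 9 turned. For single gene lists these numbers were 87, 0, 5 and 20. For words, direction came from the flank tested, so TAACTA without replicate 1 (0.998-fold by the mean of both flanks) counts as lost, not turned.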

Other observations

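The gene families and tests here were chosen after the results were seen, except the composition tests of DRE and Motif 1 and of chromosome 4, which were stated before their values. Genes for mitochondrial ribosomal proteins, encoded in the nucleus, had an IDR summit within 1000 bp of a TSS in 28 of 73 cases (38.4% against 24.4%, Fisher's exact test, adjusted p = 0.0133 over 6 families), with mRpS23 (signal 1207), mRpS10 (895) and mRpL41 (817) the strongest. The peak of mRpS23 is the one named for CenG1A. Proteasome subunits had 12 of 32 (37.5%, adjusted exact p = 0.118) and glutathione S-transferases 11 of 35 (31.4%, adjusted exact p = 0.328). The other families were low: cytochrome P450 enzymes 4 of 83 (4.82%, adjusted exact p = 1.18e-05), ionotropic receptors 2 of 60 (3.33%, adjusted exact p = 2.95e-05) and cuticular proteins of the CPR family 1 of 70 (1.43%, adjusted exact p = 8.72e-07). Of 290 tRNA genes, 20 (6.90%) had a summit within 500 bp, against 3.52% on average and at most 7.93% for random placements (unadjusted permutation p = 0.026). The placements did not keep the concentration of peaks near TSSs.

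Outside promoters the most raised 6-letter words at 5% or more of summits were GTGCAC (2.04-fold), CTACAC (2.02-fold) and ACAGTG (1.93-fold), none of them a homeodomain core. Assigned by nearest TSS, 12 of 20 segment polarity and Wnt genes had a peak (60%), against 31.3% for random lists matched on territory (adjusted permutation p = 0.0803), and 4 of 6 NK cluster genes (66.7% against 28.4%, adjusted permutation p = 0.197).

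Peaks concentrated at promoters, where DRE and Motif 1 were raised, and TAATTA was 1.40-fold higher at all summits than in flanks, a call lost outside promoters (1.14-fold) and in replicate 2 alone (0.957-fold). The higher frequency of TAATTA may come from the A and T content of summits: it ranked 14 of 14 words with the same letters. The ladybird-type word TAACTA ranked 40 of 60, with its 1.29-fold below the median of 1.35-fold. Summit composition is excluded as the cause for DRE and Motif 1, which stood above 99.8% of the words with the same letters. Signal at active promoters in general, whatever the tagged protein, stays open for the promoter peaks. A rule set after the values were seen asked for ribosomal protein genes to be raised and muscle and heart lists not to be. Ribosomal protein genes were raised (73.1% with a summit within 1000 bp of a TSS). The rule cannot decide, since muscle and heart genes may also be active in whole embryos and these lists are small. With that window none passed, but fusion and adhesion genes passed as higher in replicate 2 alone (55.6%, adjusted exact p = 0.0101; 27.8% and p = 0.931 in replicate 1), and mesoderm and heart factors passed by nearest TSS but not against lists matched on territory (adjusted permutation p = 0.12). Gene expression and a ChIP of GFP alone or of another factor were not analysed here, so Lbe binding at these promoters stays open too.

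The full replicate 1 list held 600 regions on chromosome 4 and that of replicate 2 held 91, a ratio of 6.59. If a base composition bias of the libraries were the cause, rates from the other arms would predict a ratio of at least 3 for chromosome 4. They predicted 1.44 (1.25 to 1.54 with the rates of single arms), and 1.60 (1.31 to 1.88) with windows of 5000 bp in place of 400 bp. The stated bound against this cause, 1.5, lies inside both ranges, but all predictions stay under 3, so composition may contribute but leaves most of the difference. What else sets the replicates apart there was not tested.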
